A study of Mus musculus with 9 samples.

How the data were processed

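RNA was measured by sequencing in mouse skeletal stem cells (mSSC), a progenitor population of bone and cartilage, sorted by flow cytometry from the femoral fracture callus of C57BL/6J mice 10 days after injury. Per the labels' protocols, cells were gated as negative for CD45, TER119, TIE2, THY1, 6C3 and CD105 and positive for ITGAV. Between 500 and 1000 cells were sorted per sample, cDNA was made with a kit for very low RNA input, and reads were paired ends of 76 bases. The average number of mapped reads per sample, in units of 1e+06 reads, was about 45 per the labels' protocols. The 9 libraries fall into 3 ages, 2, 12 and 24 months, with 3 libraries per age. The labels number the samples of an age but do not say whether they came from separate animals, so p-values measure only the spread between these samples, which may in part be technical.

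The deposited table holds 1 value per gene symbol and library on a log2 scale, for 53607 rows. Removing the log and an offset of 1 gave columns that each sum to 1000000, so the deposited log2 values were taken as log2(TPM + 1), where TPM is a relative abundance scaled for transcript length. Per the submitters' processing notes, the authors used Salmon and the build GRCm38.p6, and the version of Salmon, the annotation release and the way transcripts were summed to genes are not given in the sources used here. TPM keeps no library depth, so the depth of a single library is unknown, and no counting interval or count model was used. Salmon shares reads among transcripts that hold the same sequence, so values of near-identical copies and of genes nested in others are uncertain, and strand is not given in the sources used here. Of the rows, 26 carried a date in place of a symbol and were tested but not named. The column headers name the age and no replicate number, so libraries 1, 2 and 3 of an age are named in file order and were not paired across ages.

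Values were analysed as deposited, with no further scaling. Genes with at least 1 TPM in at least 3 of the 9 libraries were kept, which left 14501. One linear model with the 3 ages was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend, 6 residual degrees of freedom), and the contrasts were 24 against 2, 12 against 2 and 24 against 12 months, all two-sided. A moderated F test asked for any difference among the ages, and a second fit used age in months as a number. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes of low abundance, and are given with limma's moderated standard error (SE). Means of TPM are given with the standard deviation (SD) of 3 libraries.

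The design, the alternatives, 47 gene lists and the rule for named genes were fixed before the data were examined. The lists cover the sort gate, skeletal lineages, matrix, signalling, metabolism, stress, inflammation and markers of other cell types that a callus could hold. A list with at least 3 kept members was tested against all other kept genes with limma's camera at its preset correlation of 0.01 between genes, which left 46 lists, adjusted within each contrast. The test was repeated with the correlation estimated from the data and with fry, a rotation test of whether the genes of a list move, on balance, one way. The estimated correlation had a median of 0.227 over the lists, above the preset value, so p-values at the preset correlation may be too small. Counts of members are given over all genes and adjusted over the list alone. For 24 against 2 months the rule named up to 12 genes per direction with the largest fold change among called genes whose 3 values per age did not overlap, and up to 8 per direction for the other contrasts. Places left were filled by the smallest unadjusted p and are reported as values that did not pass. Up to 4 members of smallest p per list were named, and the gate genes and a fixed set of skeletal genes were reported whatever their test. Gene models without a gene-like name, ribosomal protein genes, pseudogenes and mitochondrial genes were counted and not named.

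Alternatives changed the offset (0.1 or 5), the filter (none, 5 TPM, or 5 libraries), the scaling (quantile, median of ratios, or rescaling without mitochondrial and the 50 most abundant genes), the variance model, the weights, the libraries in the fit and the threshold (0.10), and left out each library in turn. Restriction to protein-coding genes and removal of each library's trend on GC content and transcript length, by splines of 3 degrees of freedom, were added after seeing the data. Biotypes, coordinates, transcript lengths and GC content came from GENCODE release M21 on GRCm38, to which 98.9% of rows matched by symbol, and 99.5% of kept genes had a length and GC value. The replicate block that had been planned could not be fitted, because the columns carry no replicate number.

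The pipeline was tested on simulated data drawn from the real means and spreads of the 14501 genes for 24 against 2 months, with known changes added to the 24-month libraries. It recovered 27% of genes changed by 1 and 76% of genes changed by 2 on the log2 scale, with the right sign in 100%, and 7 of 110 calls were unchanged genes. Each gene was drawn independently and no library stood apart, unlike in the real data, so these shares need not hold there. Overlaps between comparisons that share libraries were set beside 100 simulations of unchanged groups.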

Results

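Gene expression was measured in skeletal stem cells sorted from the healing femoral fracture of mice aged 2 months (adult), 12 months (middle-aged) and 24 months (aged), 10 days after injury. Each age had 3 libraries, and the comparisons ask how the expression profile of these cells during repair differs with age. Each library held between 13387 and 13813 genes at 1 TPM or more. The depth of single libraries is unknown because TPM keeps none. Col2a1, the main collagen of cartilage, and Sparc, a matrix glycoprotein of bone, had the 2 highest means over the 9 libraries. Col2a1 stood at 39494 ± 2081, 22030 ± 3422 and 18860 ± 7515 TPM at 2, 12 and 24 months, and Sparc at 24584 ± 1442, 21727 ± 1175 and 21836 ± 278 (SD, n = 3). Itgav, the gene of the positive gate marker, stood at 46.8 ± 4.45 TPM at 2 months, 32.2 ± 5.04 at 12 months and 37.7 ± 11.6 at 24 months (SD, n = 3). It was called in no comparison (limma, smallest adjusted p = 0.290). Of the genes whose proteins were gated out, Ptprc (CD45) reached at most 0.281 TPM and Tek (TIE2) at most 0.301 TPM in any library. Thy1, Enpep (6C3) and Eng (CD105) had means between 0.582 and 2.78 TPM in every age, and none was called. Library 1 of 24 months stood apart, with a mean correlation across genes of 0.932 with the other libraries, against 0.953 to 0.962 for the rest. It also had the most rows listed at 0, 33313 against 29284 to 31082 in the other libraries. Within each age library 1 had the most such rows, 31082 at 2 months and 31003 at 12 months. Whether depth or the order of the columns plays a part could not be tested. The median SD within an age, on the log2 scale, was 0.239 at 2 months, 0.291 at 12 months and 0.338 at 24 months. Without library 1 of each age it was 0.191, 0.253 and 0.212, with 12 months the highest.

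Between 24 and 2 months, Actg2, a smooth muscle actin on chromosome 6 (83512905 to 83536265, minus strand, ENSMUSG00000059430.14), rose from 6.18 ± 1.78 to 56.4 ± 21.6 TPM (SD, n = 3). Its log2 fold change was 2.96 ± 0.45 (SE, limma adjusted p = 0.0355). Psmb8, an interferon-inducible subunit of the immunoproteasome on chromosome 17 (34197721 to 34201454, plus strand, ENSMUSG00000024338.15), rose from 2.39 ± 0.726 to 20.9 ± 10.1 TPM. Cdkn2b, an inhibitor of the cell cycle on chromosome 4 (89306299 to 89311039, minus strand, ENSMUSG00000073802.5), rose from 16.8 ± 3.81 to 46.7 ± 10.4 TPM. In all, 23 of 14501 genes were called, 13 higher and 10 lower, and 2103 had an unadjusted p under 0.05 where chance gives 725. The values of the 2 ages did not overlap for 20.2% of genes, where chance gives 10%. These chance levels, here and below, are averages. Genes are correlated, so the values by chance can vary widely around them. They were not computed for splits that mix the ages.

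Other genes that rose at 24 months were Tpm2, a tropomyosin, by 2.35 ± 0.37 on the log2 scale, the retinoic acid binding protein Crabp2 by 2.12 ± 0.33 and Glipr2 by 1.71 ± 0.26. The fatty acid binding proteins Fabp4 and Fabp5 rose by 1.68 ± 0.26 and 0.90 ± 0.15. Serping1, the inhibitor of complement C1, rose by 1.47 ± 0.22, the small proteoglycan Aspn by 1.45 ± 0.22 and the lysosomal protease Ctsh by 0.80 ± 0.13. Genes that fell were the amino acid transporter Slc38a4, with -2.15 ± 0.35, the small nucleolar RNA Snord91a with -2.10 ± 0.35, the RNA-binding protein gene Qk with -1.68 ± 0.23 and Ctsw with -1.60 ± 0.22. Egln1, an oxygen-sensing prolyl hydroxylase, fell with -1.37 ± 0.19, Otud7b with -1.35 ± 0.23, the transcription factor Klf2 with -1.12 ± 0.18 and the matrix protein Prelp with -0.89 ± 0.13. Adjusted p over these genes ranged from 0.0307 to 0.0474 (limma). The next genes did not pass: Dkk3 had 1.84 ± 0.33 (adjusted p = 0.0655), Cdsn -2.35 ± 0.40 (0.0528), Chad -1.38 ± 0.25 (0.0768), Krt16 -1.77 ± 0.33 (0.0797) and Scube1 -1.60 ± 0.31 (0.0957). The count of 23 was 2, 3 and 1 without library 1, 2 or 3 of 2 months, 50 and 3 without library 1 or 3 of 12 months, and 1, 5 and 430 without library 1, 2 or 3 of 24 months. It was 5 with an offset of 0.1, 0 without a filter, 3 without the intensity trend and 295 with array quality weights.

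**Figure D1:**
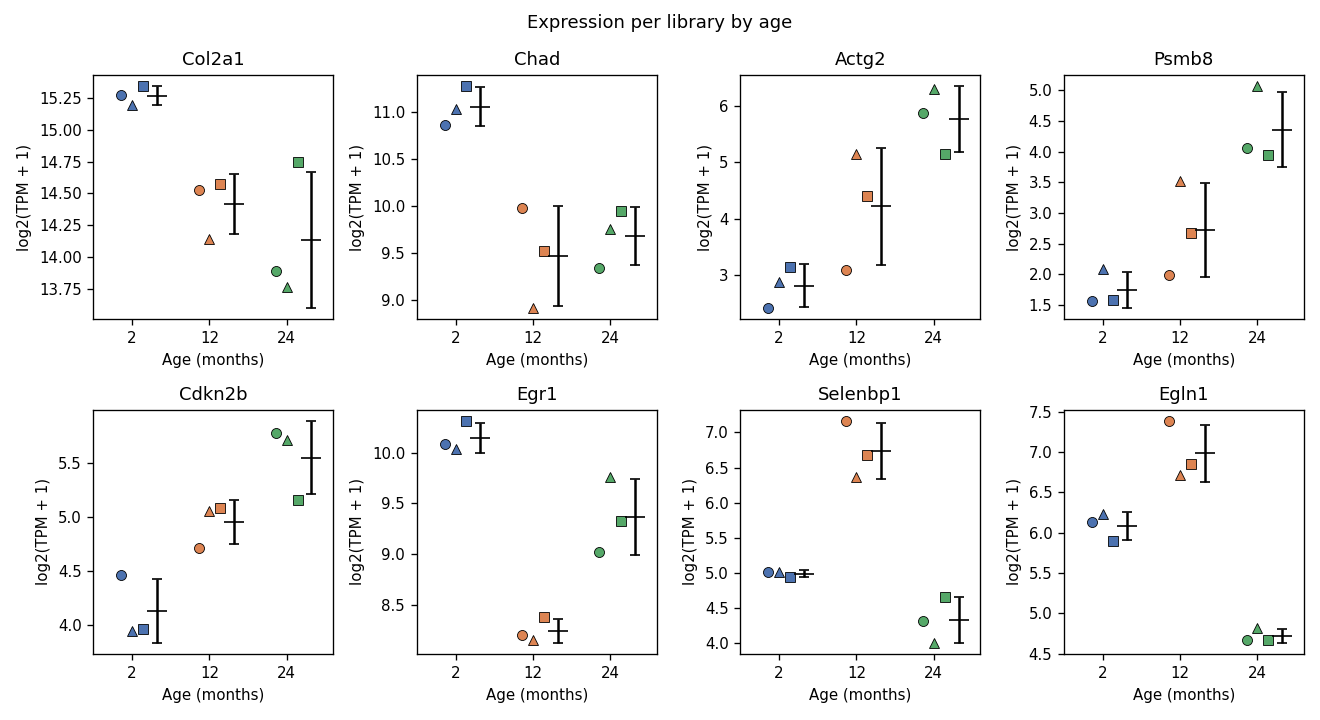
Expression of 8 genes in each library, as log2(TPM + 1) on the y axis against age in months on the x axis. Circles, triangles and squares are libraries 1, 2 and 3 of an age in file order, the bar beside them is the mean with SD (n = 3), and Actg2 is higher at 24 than at 2 months by 2.96 in the mean.

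Cartilage genes were lower at 24 than at 2 months. All 24 chondrocyte genes had a negative log2 fold change, with a median of -0.80 (camera adjusted p = 5.89e-14 at the preset correlation, adjusted p = 0.374 with an estimated correlation). Of them 18 were lower when adjusted over the list alone and 0 over all genes. Col2a1 stood at 39494 ± 2081 TPM at 2 months and 18860 ± 7515 at 24 months (SD, n = 3), a log2 fold change of -1.13 ± 0.27 (limma adjusted p = 0.14). Sox9, the master regulator of cartilage, had -0.68 ± 0.21 (0.212) and the proteoglycan Acan -0.69 ± 0.18 (0.161). The median was -0.66 without library 1 of 24 months, the library that stood apart. The 12 hypertrophic cartilage genes had a median of -0.77 (camera adjusted p = 1.94e-04, adjusted p = 0.396 with an estimated correlation), 0 of them passing over all genes or adjusted over the list alone. That median was -0.45 without library 1 of 24 months, and Col10a1 had -1.07 ± 0.42. The 22 osteoblast genes were not called (median -0.27, camera adjusted p = 0.121). Runx2 had -0.52 ± 0.28, Sp7 -0.31 ± 0.32, Bglap -0.04 ± 0.68, Ibsp 0.03 ± 0.49 and Spp1 -0.28 ± 0.43, none of which passed.

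Contractile markers were higher. Of 15 smooth muscle and pericyte markers, 13 had a positive log2 fold change at 24 against 2 months, with a median of 1.59 (camera adjusted p = 8.66e-08, adjusted p = 0.374 with an estimated correlation). Actg2 passed over all genes and 9 when adjusted over the list alone. Acta2, smooth muscle actin, had 2.50 ± 0.63 and Myl9 2.31 ± 0.58 (limma adjusted p = 0.153 for each). Another check took 8 genes of the same fixed list by their mean TPM. Of these, 6 had a mean of 1 TPM or more at 24 months that was above the mean at 2 months, and 3 had such a mean at 12 months. The 3 varied widely between libraries at 12 months, with Rgs5 at 6.05 ± 6.26 TPM (SD, n = 3). The 8 skeletal muscle markers had a median of 0.98 (camera adjusted p = 1.94e-04, adjusted p = 0.374 with an estimated correlation). Of these 3 were higher when adjusted over the list alone and 0 over all genes, with Des at 1.59 ± 0.35 and Myl1 at 2.19 ± 0.49. Des is also a member of the smooth muscle and pericyte list.

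Cell cycle lists were higher at 24 months. All 25 proliferation genes had a positive log2 fold change against 2 months, with a median of 0.65 (camera adjusted p = 2.62e-10, adjusted p = 0.374 with an estimated correlation). Of them 8 were higher when adjusted over the list alone and 0 over all genes. Prc1, which organises the spindle midzone, had 0.91 ± 0.17 (limma adjusted p = 0.0797), the mitotic cyclin Ccnb1 0.97 ± 0.25 and Mki67 0.41 ± 0.30. The 25 DNA replication genes had a median of 0.46 (camera adjusted p = 1.18e-07, adjusted p = 0.374 with an estimated correlation). Of these 3 were higher when adjusted over the list alone and 0 over all genes, led by the helicase subunit Mcm3 with 1.35 ± 0.34.

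Lists of inflammatory and secreted factors were also higher at 24 than at 2 months. These lists share members: Ccl2 and Il6, for example, belong to the senescence, cytokine and NF-kB lists alike. The 21 senescence-associated genes had a median of 0.78 (camera adjusted p = 2.06e-05, adjusted p = 0.374 with an estimated correlation), with Cdkn2b called over all genes, 8 higher when adjusted over the list alone, and the chemokine Cxcl5 at 2.53 ± 0.52. Cdkn1a had -0.55 ± 0.22, and Cdkn2a, below the floor for testing, stood at 0.0938 ± 0.163 TPM at 2 months and 1.20 ± 0.765 at 24 months (SD, n = 3). The 18 osteoclast-regulating and myeloid cytokines had a median of 0.64 (camera adjusted p = 0.00155, adjusted p = 0.374 with an estimated correlation), 4 higher when adjusted over the list alone and 0 over all genes. Among them the chemokine Ccl7 had 2.48 ± 0.53 and Csf1, the growth factor of osteoclast precursors, 1.00 ± 0.36 (limma adjusted p = 0.260). Tnfsf11 (RANKL) had 0.53 ± 0.35 and its decoy receptor Tnfrsf11b 0.14 ± 0.28. The 23 NF-kB targets had a median of 0.27 (camera adjusted p = 1.94e-04, adjusted p = 0.374 with an estimated correlation), with 5 higher when adjusted over the list alone and 0 over all genes. The 21 interferon-stimulated genes had a median of 0.45 (6.15e-05, adjusted p = 0.374 with an estimated correlation), with Psmb8 called over all genes, 5 when adjusted over the list alone, and Ifitm3 at 1.98 ± 0.41. The 12 complement genes had a median of 0.64 (1.25e-04, adjusted p = 0.374 with an estimated correlation), with Serping1 called over all genes and 3 when adjusted over the list alone. Macrophage and monocyte markers, not called, had a median of 0.57 (camera adjusted p = 0.0596), 3 higher and 1 lower when adjusted over the list alone. The cytokine call was lost without library 2 of 24 months (camera adjusted p = 0.0625), and its median was 0.97 without library 3. The senescence median was 0.50 without library 1 of 24 months, the NF-kB median 0.54 without library 3 of 24 months and the interferon median 0.28 without library 1 of 2 months.

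Immediate early and dissociation response genes, which are induced within minutes of stimulation or tissue handling, were lower at 24 than at 2 months. Of 26 genes 22 were negative, with a median of -0.47 (camera adjusted p = 7.06e-09, adjusted p = 0.374 with an estimated correlation). Klf2 passed over all genes and 11 when adjusted over the list alone. With an estimated correlation the adjusted p of the lists that follow ranged from 0.374 to 0.611. Higher medians were found for genes of oxidative phosphorylation (0.28), the proteasome (0.27), ribosomal proteins (0.25), collagens (0.39), matrix proteases (0.32) and stem and progenitor genes (0.27), the last with Aspn called. Adipocyte and marrow stroma genes (0.28), with Fabp4 called, endothelial markers (0.62) and tendon and fibroblast markers (0.55) were higher as well. Lower medians were found for hypoxia and glycolysis genes (-0.31) and class II antigen presentation genes (-0.59). The median was 0.21 for proteases without library 1 of 2 months, and 0.44 for stem and progenitor genes without library 3 of 2 months or library 3 of 24 months. The adipocyte call was lost without library 2 of 24 months (camera adjusted p = 0.0914), and the median was 0.45 without library 1. The tendon call was lost without library 1 of 24 months (0.485) or library 1 of 2 months (0.198). The endothelial call was lost without library 1 (0.0771) or 3 (0.0688) of 2 months or library 3 of 24 months (0.124), with a median of 0.97 without library 2 of 2 months. The hypoxia call was lost without library 2 of 2 months (0.0631) or library 2 of 24 months (0.245). Its median was -0.48 without library 1 of 2 months, -0.18 without library 1 of 24 months and -0.47 without library 3. The class II call was lost without library 1 of 2 months (0.190) or library 1 (0.0501) or 2 (0.0859) of 24 months. In all, 23 of 46 lists were called, 18 higher and 5 lower, against 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, and 0 with fry (limma). Pparg had 0.77 ± 0.35, Igf2 -0.86 ± 0.46 and H19 0.09 ± 0.24, none of which passed.

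**Figure D2:**
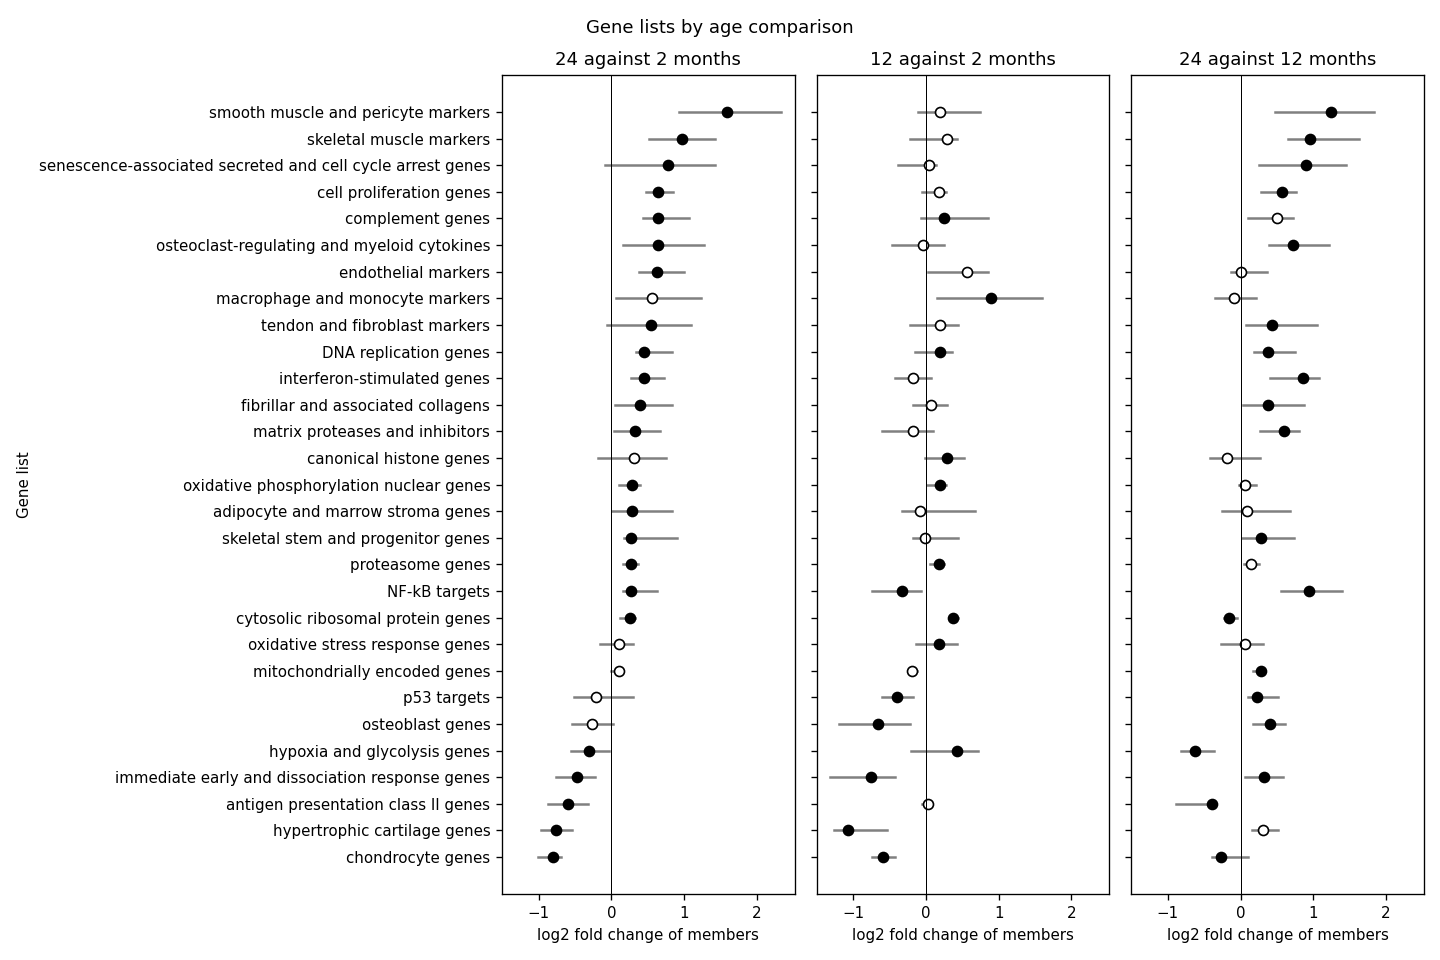
Median log2 fold change of the members of each gene list called in at least 1 comparison (point) with the range from the 25th to the 75th percentile (line) on the x axis, in 1 panel per age comparison. Filled points are lists called by camera at the preset correlation and open points are not, and chondrocyte genes lie at -0.80 and smooth muscle and pericyte markers at 1.59 for 24 against 2 months.

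Between 12 and 2 months, genes of the immediate early response were lower in middle-aged mice. Egr1, an early growth response transcription factor on chromosome 18 (34859823 to 34864984, plus strand, ENSMUSG00000038418.7), fell from 1134 ± 120 to 302 ± 25.7 TPM (SD, n = 3), a log2 fold change of -1.90 ± 0.18 (limma adjusted p = 0.00201). Egr2 fell with -2.50 ± 0.30, Fosb with -1.90 ± 0.27 and Zfp36, which destabilises inflammatory mRNAs, with -1.63 ± 0.20. Of the 26 genes of this list 23 were negative, with a median of -0.75 (camera adjusted p = 1.02e-14, adjusted p = 0.625 with an estimated correlation, 0.0310 with fry). Over all genes 10 were lower, and 17 were lower and 1 higher when adjusted over the list alone. In all, 105 genes were called, 38 higher and 67 lower, and 2267 had an unadjusted p under 0.05 where chance gives 725. The values of the 2 ages did not overlap for 25% of genes, where chance gives 10%. With median-of-ratios scaling 58 genes were higher and 57 lower.

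Fabp4 rose from 17.3 ± 6.83 to 90.4 ± 17.8 TPM at 12 months (SD, n = 3, log2 fold change 2.37 ± 0.26, limma adjusted p = 0.00245). The selenium binding protein Selenbp1 rose by 1.75 ± 0.22, the steroid dehydrogenase Hsd17b1 by 2.15 ± 0.36, Bend5 by 1.82 ± 0.33, Crabp2 by 1.74 ± 0.33, the desmosomal protein Pkp2 by 1.71 ± 0.33 and platelet factor Pf4 by 2.03 ± 0.40. Arhgap27os2, an antisense transcript whose reads cannot be told from those of its partner without strand, had 2.21 ± 0.35. Genes that fell included Slc38a4 with -1.88 ± 0.35, the thrombin receptor Thbd with -1.82 ± 0.26 and the phosphatase Dusp5 with -1.76 ± 0.23. The small RNA genes Mir3109 and Snord91a were listed at 0 in all 3 libraries of 12 months. At 2 months Mir3109 stood at 7.17, 3.43 and 8.96 TPM and Snord91a at 6.95, 5.47 and 5.86 TPM in the 3 libraries. The count of 105 was 33, 30 and 17 without library 1, 2 or 3 of 2 months and 46, 41 and 38 without library 1, 2 or 3 of 12 months. It was 220 and 213 without library 1 or 3 of 24 months, 270 in a fit of the 6 libraries of these ages and 15 without the intensity trend.

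Cartilage and bone lists were lower at 12 than at 2 months. The hypertrophic and osteoblast lists share Alpl, Ibsp and Pth1r, so their calls are not independent. Of 24 chondrocyte genes 23 were negative, with a median of -0.59 (camera adjusted p = 9.34e-07, adjusted p = 0.625 with an estimated correlation), and 6 were lower when adjusted over the list alone. Chad, a cartilage matrix protein, passed over all genes with -1.58 ± 0.25 (limma adjusted p = 0.0170), while Col2a1 had -0.85 ± 0.27 (0.159), Sox9 -0.44 ± 0.21 and Acan -0.38 ± 0.18. All 12 hypertrophic cartilage genes were negative, with a median of -1.07 (camera adjusted p = 1.40e-05, adjusted p = 0.625 with an estimated correlation), 8 passing when adjusted over the list alone and 0 over all genes, and Col10a1 had -1.22 ± 0.42. Of 22 osteoblast genes 19 were negative, with a median of -0.66 (camera adjusted p = 0.00179, adjusted p = 0.625 with an estimated correlation), 5 passing when adjusted over the list alone and 0 over all genes. Runx2, the master regulator of the osteoblast lineage, had -0.90 ± 0.28, Sp7 -0.72 ± 0.32, Bglap -1.85 ± 0.68, Ibsp -0.18 ± 0.49 and Spp1 -0.05 ± 0.43. Without library 2 of 12 months the median was -0.67 for the hypertrophic and -0.38 for the osteoblast list.

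Metabolic and stress genes moved both ways at 12 against 2 months. The 25 hypoxia and glycolysis genes had a median of 0.43 (camera adjusted p = 5.19e-05, adjusted p = 0.663 with an estimated correlation). Ankrd37 passed over all genes with 1.35 ± 0.27, and 11 genes were higher and 1 lower when adjusted over the list alone. The metallothioneins Mt1 and Mt2, which bind zinc and copper, rose by 1.5 ± 0.26 and 1.65 ± 0.28, and Srxn1, a repair enzyme of peroxiredoxins, fell with -1.48 ± 0.22. They belong to the oxidative stress list, whose median was 0.18 (camera adjusted p = 0.0148, adjusted p = 0.625 with an estimated correlation), with 4 higher and 1 lower when adjusted over the list alone. That median was 0.30 without library 2 and 0.11 without library 3 of 12 months. The 32 ribosomal protein genes were all positive (median 0.37, camera adjusted p = 1.29e-13, adjusted p = 0.625 with an estimated correlation), 4 passing when adjusted over the list alone and 0 over all genes. NF-kB targets were lower (median -0.33, camera adjusted p = 0.00528, adjusted p = 0.625 with an estimated correlation), with Irf1 at -1.01 ± 0.18 and Bcl3 at -1.15 ± 0.23 called over all genes and 5 when adjusted over the list alone. The p53 targets were lower too (median -0.40, 0.0110, adjusted p = 0.625 with an estimated correlation), with Btg2 at -1.26 ± 0.22 called over all genes and 4 when adjusted over the list alone. Btg2 is also a member of the immediate early list. The p53 call was lost without library 2 of 12 months (camera adjusted p = 0.0837).

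Macrophage and monocyte markers were higher at 12 than at 2 months (median 0.89, camera adjusted p = 0.0332, adjusted p = 0.625 with an estimated correlation), 3 higher and 2 lower when adjusted over the list alone and 0 over all genes. They stood near the floor, with Tyrobp at 3.37 ± 1.94 and Ctss at 2.41 ± 1.32 TPM at 12 months (SD, n = 3). C1qb was listed at 0 in all libraries of 2 months and stood at 1.28, 6.12 and 2.37 TPM at 12 months. This call was lost without library 3 of 2 months (0.0518), library 2 (0.104) or library 3 (0.0887) of 12 months. Higher medians were also found for histones (0.29), with the variant histone gene H2afz called at 0.91 ± 0.17, oxidative phosphorylation (0.19), proteasome (0.18), DNA replication (0.20) and complement genes (0.24). For these the adjusted p ranged from 0.625 to 0.759 with an estimated correlation. Without library 2 of 12 months camera's adjusted p was 0.375, 0.0931, 0.0809, 0.695 and 0.236 for the 5 lists in that order. Without library 3 of 2 months it was 0.219, 0.0580, 0.0518 and 0.227 for the first 4. The DNA replication call was also lost without library 1 of 2 months (0.0800), and its median was 0.38 without library 2 of 2 months and 0.43 without library 1 of 12 months. The complement call was also lost without library 1 (0.0581) or 2 (0.0831) of 2 months or library 3 of 12 months (0.0985). Its median was 0.57 without library 3 of 2 months and 0.73 without library 1 of 12 months. As fixed, the complement list and the macrophage and monocyte list share C1qa, C1qb and C1qc. In all, 15 lists were called, 9 higher and 6 lower, against 0 with an estimated correlation, where 1 had an unadjusted p under 0.05, and 1 with fry (limma). H19 had 0.92 ± 0.24, Csf1 -0.53 ± 0.36, Tnfsf11 -0.14 ± 0.35, Tnfrsf11b -0.30 ± 0.28, Cdkn1a -0.14 ± 0.22, Pparg 0.68 ± 0.35, Igf2 -0.13 ± 0.46 and Mki67 0.14 ± 0.30, none of which passed.

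Between 24 and 12 months, Egln1, on chromosome 8 (124908587 to 124949324, minus strand, ENSMUSG00000031987.6), fell from 129 ± 33.4 to 25.4 ± 1.64 TPM (SD, n = 3), a log2 fold change of -2.27 ± 0.19 (limma adjusted p = 7.51e-04). Selenbp1 fell from 108 ± 31.3 to 19.4 ± 4.65 TPM, with -2.41 ± 0.22. Tnfaip3, an inhibitor of NF-kB signalling, and the interferon regulatory factor Irf1 rose by 1.79 ± 0.29 and 1.25 ± 0.18. In all, 66 genes were called, 22 higher and 44 lower, and 2051 had an unadjusted p under 0.05 where chance gives 725. The values of the 2 ages did not overlap for 17.2% of genes, where chance gives 10%. With median-of-ratios scaling 18 genes were higher and 82 lower, and with quantile normalization 20 and 70.

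The acute phase protein Saa3 rose by 2.90 ± 0.54, the nucleic acid sensor Zbp1 by 2.02 ± 0.38, the circadian repressor Nr1d1 by 1.77 ± 0.26, Egr2 by 1.67 ± 0.30, Bcs1l by 1.37 ± 0.24 and Arid5a by 1.25 ± 0.21 at 24 against 12 months. Espn, an actin-bundling protein, fell with -4.20 ± 0.65, the metabolic hormone Fgf21 with -2.95 ± 0.46, the carbonic anhydrase Car6 with -2.93 ± 0.42, Cox6a2 with -2.37 ± 0.39 and Cdsn with -2.31 ± 0.40. The small nucleolar RNA AF357425 was listed at 0 in all 3 libraries of 24 months and stood at 3.96, 6.48 and 1.94 TPM at 12 months. The count of 66 was 31 without library 1 of 2 months, 6, 105 and 3 without library 1, 2 or 3 of 12 months and 12, 2 and 345 without library 1, 2 or 3 of 24 months. It was 2 in a fit of the 6 libraries of these ages, 0 without a filter and 4 without the intensity trend.

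Hypoxia and glycolysis genes were lower at 24 than at 12 months in 22 of 25 members (median -0.62, camera adjusted p = 2.58e-13, adjusted p = 0.463 with an estimated correlation), 17 passing when adjusted over the list alone and 0 over all genes. Bnip3, a mitophagy receptor, had -1.50 ± 0.29 and Gapdh -0.78 ± 0.17. Of 23 NF-kB targets 21 were positive (median 0.95, camera adjusted p = 1.75e-10, adjusted p = 0.463 with an estimated correlation). Irf1 and Tnfaip3 passed over all genes and 16 when adjusted over the list alone. The senescence list had a median of 0.91 (camera adjusted p = 4.12e-06, adjusted p = 0.463 with an estimated correlation), with 11 higher when adjusted over the list alone and Cxcl5 at 2.47 ± 0.52. The interferon list had a median of 0.85 (9.71e-06, adjusted p = 0.463 with an estimated correlation), with 9 higher when adjusted over the list alone. Matrix proteases had a median of 0.60 (4.12e-06, adjusted p = 0.463 with an estimated correlation), with 7 higher when adjusted over the list alone and Adamts4, which cleaves aggrecan, at 1.63 ± 0.34. None of the last 3 lists had a member called over all genes. The protease median was 0.39 without library 2 of 24 months.

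Smooth muscle and pericyte markers were higher at 24 than at 12 months (median 1.25, camera adjusted p = 8.36e-06, adjusted p = 0.484 with an estimated correlation), 9 passing when adjusted over the list alone and 0 over all genes. Skeletal muscle markers had a median of 0.95 (0.00590, or 0.463 with an estimated correlation). Cytokines had a median of 0.72 (camera adjusted p = 0.00224, or 0.484 with an estimated correlation), with Csf1 at 1.52 ± 0.36 (limma adjusted p = 0.0952), Tnfsf11 at 0.66 ± 0.35 and Tnfrsf11b at 0.44 ± 0.28. Proliferation genes had a median of 0.56 (camera adjusted p = 1.25e-05, or 0.660 with an estimated correlation), with 1 passing when adjusted over the list alone. Immediate early genes had a median of 0.32 (6.06e-04, or 0.582 with an estimated correlation), with Egr1, Zfp36 and Egr2 called over all genes and 8 when adjusted over the list alone. The smooth muscle and proliferation medians were 0.78 and 0.35 without library 1 of 12 months. Without library 2 of 24 months the cytokine call was lost (camera adjusted p = 0.0502) and the immediate early median was 0.18.

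The chondrocyte list had a median of -0.26 at 24 against 12 months (camera adjusted p = 0.00946, or 0.671 with an estimated correlation). Its call was lost without library 1 of 12 months (0.123) and library 1 (0.0835) or 2 (0.508) of 24 months, and the median was -0.41 without library 2 of 12 months and -0.54 without library 3 of 24 months. Col2a1 had -0.28 ± 0.27, Sox9 -0.24 ± 0.21, Acan -0.31 ± 0.18 and Col10a1 0.15 ± 0.42. The osteoblast list had a median of 0.41 (camera adjusted p = 0.0445, or 0.660 with an estimated correlation). Its call was lost without library 1 of 2 months (0.0529), library 2 of 12 months (0.623) or library 2 of 24 months (0.401). Runx2 had 0.38 ± 0.28, Sp7 0.41 ± 0.32, Bglap 1.81 ± 0.68, Ibsp 0.21 ± 0.49 and Spp1 -0.23 ± 0.43. Cdkn1a had -0.40 ± 0.22, H19 -0.83 ± 0.24, Igf2 -0.73 ± 0.46, Pparg 0.09 ± 0.35 and Mki67 0.27 ± 0.30, and none of these single genes passed.

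Another 8 lists were called at 24 against 12 months, with an adjusted p of 0.463 for class II genes and 0.660 for the other 7 with an estimated correlation. Collagens (0.38), tendon markers (0.43), DNA replication (0.38), p53 targets (0.22), mitochondrially encoded genes (0.27) and stem and progenitor genes (0.29) had higher medians. Ribosomal protein genes (-0.16) and class II genes (-0.40) had lower ones. Each of the 8 calls was lost without at least 1 library. Without library 1 of 12 months camera's adjusted p was 0.123 for tendon, 0.292 for DNA replication and 0.0978 for stem and progenitor genes. Without library 2 of 12 months it was 0.370 for ribosomal proteins, 0.293 for p53 targets and 0.0527 for mitochondrial, class II and stem and progenitor genes alike. Without library 3 of 12 months it was 0.0508 for p53 targets. Without library 1 of 24 months it was 0.111 for collagens, 0.310 for tendon, 0.0772 for p53 and 0.183 for stem and progenitor genes. Without library 2 of 24 months it was 0.228 for p53 and 0.186 for stem and progenitor genes, and without library 3 it was 0.0970 for mitochondrial genes. Medians of calls that held moved to -0.61 (class II) without library 1 of 12 months, 0.68 (tendon) without library 2, and -0.26 (ribosomal) and 0.45 (stem and progenitor) without library 3. They moved to -0.25 (class II) without library 1 of 24 months, and -0.66 (class II) and 0.41 (p53) without library 3. In all, 20 lists were called, 16 higher and 4 lower, against 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, and 0 with fry (limma).

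**Figure D3:**
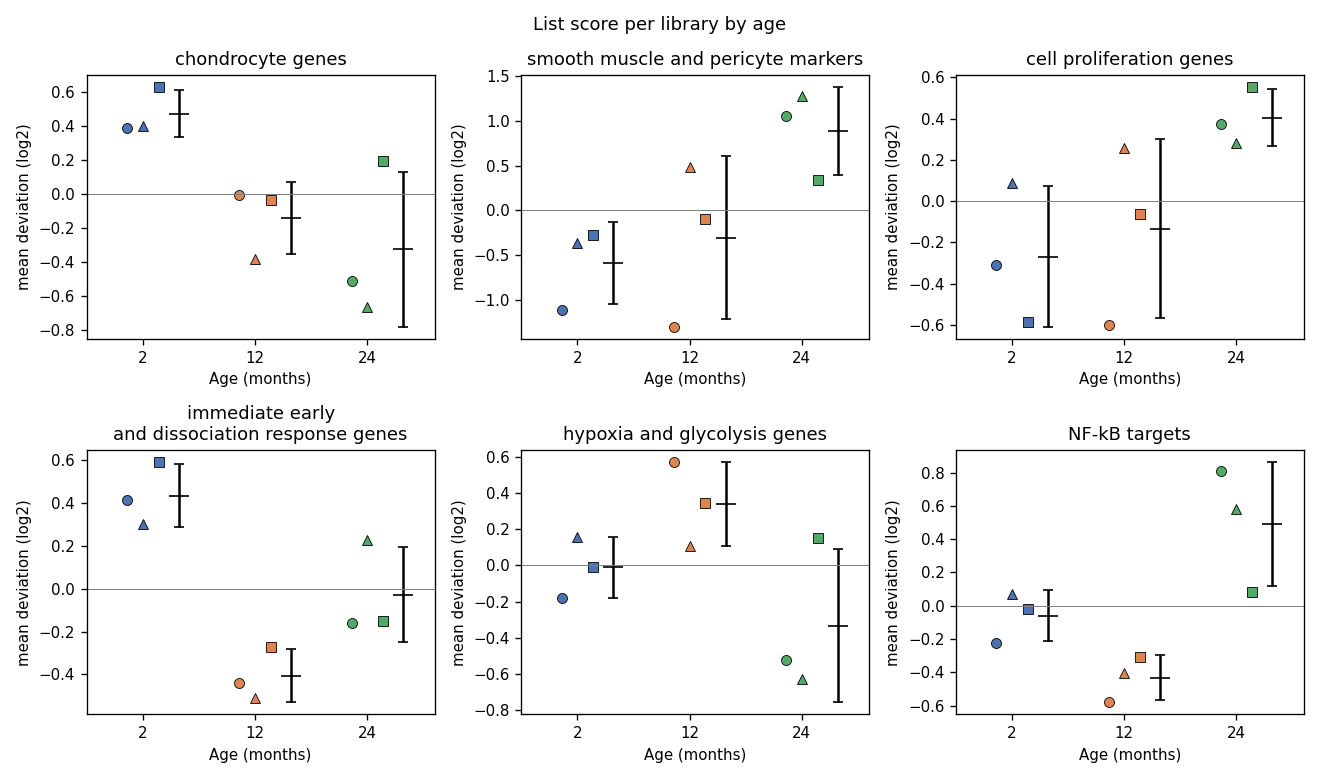
Score of 6 gene lists in each library, as the mean deviation of the members from their mean over the 9 libraries (log2) on the y axis, against age in months on the x axis. Circles, triangles and squares are libraries 1, 2 and 3 of an age in file order, the bar beside them is the mean with SD (n = 3), and the chondrocyte score of library 3 of 24 months, 0.191, is the highest of its age and below all 3 libraries of 2 months.

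Across the 3 ages, 110 genes differed by limma's F test at an adjusted p under 0.05, and 2631 had an unadjusted p under 0.05 where chance gives 725. The count was 26, 25 and 24 without library 1, 2 or 3 of 2 months, 73 and 22 without library 1 or 3 of 12 months, and 52 and 676 without library 2 or 3 of 24 months. With age in months as a straight line 0 genes passed (limma), with 9 at an adjusted p under 0.10 and 1767 at an unadjusted p under 0.05. Without library 3 of 24 months 143 genes had such a trend, and without library 1 of 12 months 24 did.

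Both older ages were compared with the same 2-month libraries. The 2 comparisons shared 10 called genes, 5 higher and 5 lower in both, among them Crabp2, Ctsh, Fabp4, Fabp5, Prelp, Slc38a4 and Snord91a. The pseudogene Gm11966 was another of the higher genes and had the largest changes, 4.10 at 24 and 4.36 at 12 months. Its sequence is shared with Atp5j, so its call may come from the way shared reads were divided. Gm22738 and Frg2f4 were lower in both. Independent lists would share 0.0341 higher and 0.0462 lower. Simulated unchanged groups shared 0, which sets no level for lists that do hold calls. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.508, against a median of 0.503 in 100 simulations. Their covariance was 0.123 against 0.0687, a difference of 0.0543. The 3 control libraries are too few to split, so part of the excess may come from the shared controls.

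Likewise, 22 genes were called both at 12 against 2 and at 24 against 12 months, all in opposite directions, among them Selenbp1, Mt1, Mt2, Egr1, Egr2, Zfp36, Irf1, Nr1d1, Bend5 and Hsd17b1. These comparisons share the 12-month libraries, which favours opposite signs. Independent lists would give 0.217, and simulated unchanged groups shared 0 called genes, which sets no level for lists that do hold calls. Over all genes, which are not independent replicates, 65.6% had opposite signs against a median of 66.7% in 100 simulations. The correlation was -0.463 against a simulated median of -0.499, the least negative simulation giving -0.476, and the covariance was -0.109 against -0.0682.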

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

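Restriction to protein-coding genes and removal of GC content and length trends were chosen after seeing the data. Library numbers name columns in file order. No paired analysis was possible because the columns carry no replicate number. Of the counts under alternatives 95 stayed within 1.5 times the value reported and 72 did not. Of single-gene results 6355 kept their side of the threshold, 488 lost it and 260 gained it, and 47 changed sign, all of them uncalled. Of list results the counts were 1951, 182 and 56, and 98 of 2193 medians changed sign, 4 of them with a call on either side. The single-gene results pool called and uncalled genes. Of the 23 genes called at 24 against 2 months, 2, 2 and 1 stayed called without library 1, 2 or 3 of 2 months. Without library 1, 2 or 3 of 12 months 23, 19 and 3 did, and without those of 24 months 1, 2 and 23. At 12 against 2 months the medians of DNA replication genes (0.20) and histones (0.29) ranged from -0.0169 to 0.425 and from -0.0111 to 0.426 over the libraries left out, the lowest without library 2 of 12 months, where both calls were lost. The medians of 2 lists not called as reported ranged from -0.561 to 0.955 (erythroid, 24 against 2 months, 0.05) and from -0.100 to 0.299 (stem and progenitor, 12 against 2 months, -0.02). They were called at -0.561 without library 1 of 24 months and at 0.299 without library 1 of 12 months. The values that follow are genes for 24 against 2, 12 against 2 and 24 against 12 months (reported: 23, 105 and 66), genes by the F test (110) and by the linear trend (0, with 1767 at an unadjusted p under 0.05, limma). The cause was not tested unless given. An offset of 0.1 gave 5, 57 and 43 genes by comparison and 1 by trend. With no filter the counts were 0, 8 and 0 and 0 by F, with more genes tested. A floor of 5 TPM gave 171 by F and 8 by trend. Median-of-ratios scaling gave 100 for 24 against 12 months. Without the intensity trend the counts were 3, 15 and 4 and 14 by F. Array quality weights gave 295, 370 and 336, 885 by F and 24 by trend. A fit of only the 2 ages gave 270 for 12 against 2 and 2 for 24 against 12 months. An adjusted p under 0.10 gave 39, 405 and 239, 404 by F and 9 by trend, by its looser threshold. Protein-coding genes alone gave 166 for 12 against 2 and 125 for 24 against 12 months, 213 by F and 9 by trend. GC and length removal gave 107 for 24 against 12 months. Leaving out each library gave 1 to 430, 17 to 220 and 2 to 345 genes, 22 to 676 by F and 0 to 143 by trend. It gave 8 to 23 lists for 12 against 2 months, where 15 were called. With an estimated correlation 0 lists were called in each comparison, and with fry 0, 1 and 0. The overlap of 10 genes was 7 with a floor of 5 TPM. TPM keeps no depth, so no counting error could be set beside a value, and low genes are the least certain.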

Other observations

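The test of blood cells and the count of orders for the linear trend were chosen only after the result was seen, and the removal of GC content and length trends after seeing the data. After the result was seen, the bound for blood cells was also changed, a real count of 0 was set apart for the linear trend, the spread was added to the clock test, and 2 explanations were narrowed to the chondrocyte list. The spread weighed for the heat shock genes was not in their written bound either. Signalling lists were not called in any comparison. At 12 against 2 months 18 of 21 Wnt pathway genes had a negative log2 fold change, with a median of -0.49 (camera adjusted p = 0.0513, adjusted p = 0.625 with an estimated correlation). Frzb, a secreted Wnt antagonist of cartilage, had -1.34 ± 0.32 (limma adjusted p = 0.0831). Of 10 Hedgehog pathway genes 9 were negative, with a median of -0.34 (camera adjusted p = 0.0908), and Ihh, the ligand of prehypertrophic chondrocytes, had -1.43 ± 0.46. Of 27 BMP and TGF-beta pathway genes 6 were lower when adjusted over the list alone and 0 over all genes, with a median of -0.41 (0.114), the receptor gene Tgfbr2 standing at -0.87 ± 0.22. At 24 against 12 months the Wnt median was 0.37 (0.0737).

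Markers of other cell types gave further values that did not pass. Neutrophil markers had a median of 0.91 at 24 against 2 months (camera adjusted p = 0.171) and 1.04 at 12 against 2 months (0.0940). Osteoclast markers had a median of 0.62 at 24 against 12 months (0.0800) and erythroid markers -0.52 (0.0546).

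Gm11966, an 87-base processed pseudogene that the naming rule leaves out and that was chosen after its values were seen, was listed at 0 in all 3 libraries of 2 months and had a mean of 18.8 TPM over the 6 older libraries. Nnt carries a deletion in C57BL/6J, and its larger log2 fold change against 2 months was 0.018 (limma SE 0.28), where the prediction needed more than 1. This argues against older mice of a substrain without the deletion beside 2-month mice with it. Substrains or colonies alike in Nnt were not tested. All 57 of the 31-base words of Gm11966, or 100%, also occur in Atp5j, so the values may come from the way shared reads were divided. Of 84 choices of 3 libraries, other choices gave up to 4 genes listed at 0 in those libraries and at 1 TPM or more in the rest, against 1 for the 2-month libraries. A difference with age stays open and was not tested apart from the shared sequence.

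The lower chondrocyte list at 24 months was weighed with the higher contractile, proliferation and inflammatory lists, and for the chondrocyte part library 1 of 24 months as the sole source is argued against by a median of -0.661 without it, and GC content and length by a median of -0.811 after their removal, while no bound was set for the other parts, whose medians without that library were 1.41 (smooth muscle and pericyte), 0.69 (proliferation), 0.50 (senescence) and 0.20 (NF-kB). Blood cells stay open: Ptprc had at most 0.00537 TPM in a 24-month library and CD45 was gated out, which met the first bound of under 1 TPM, but that bound rested on 1 gene, and at 24 against 2 months the macrophage, neutrophil and lymphocyte medians were 0.57, 0.91 and 0.10 (camera adjusted p = 0.0596, 0.171 and 0.685). Smooth muscle cells or pericytes carried through the sort could account for the contractile part, and the bound set for them was met. Of 8 marker genes, 6 reached 1 TPM at 24 months and were above their 2-month mean. Kcnj8 (1.13, SD 1.48) and Notch3 (1.19, SD 0.763) barely did so, and Cspg4 went from 104 to 83.3 TPM. All 8 belong to the smooth muscle and pericyte list whose rise was to be explained. They therefore cannot tell carried-through cells from sorted cells that express these genes. At 2, 12 and 24 months Myh11 had 4.99, 2.10 and 11.9 TPM and Rgs5 0.711, 6.05 and 7.98. Higd1b and Kcnj8 had 2.81 and 1.28 TPM at 12 months. So 3 of the 8 had means over 1 TPM and over their 2-month mean at 12 months. These 3 means were uncertain, with SDs of 6.26 (Rgs5), 2.65 (Higd1b) and 0.863 (Kcnj8) at 12 months. At that age the smooth muscle and pericyte list was not called (median 0.19, camera adjusted p = 0.318). A change of the sorted cells with age stays open and was not tested apart from these.

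The lower immediate early list at 12 months came with Nr1d1 at -1.66 ± 0.26 (limma adjusted p = 0.0170). A different time of day stays open: 2 of 7 output genes moved with Nr1d1, under the bound of 4, but within 1 SE up to 6 could, since Dbp, Per2 and Per3 lay within 1 SE of 0 and Hlf was not tested, while Nr1d2 had -0.80 ± 0.24, Ciart 1.08 ± 0.29 and Arntl 0.01 ± 0.21. A single library is argued against by medians of -0.71, -0.71 and -0.79 without library 1, 2 or 3 of 12 months, the largest adjusted p being 4.65e-13 with camera at the preset correlation, while with an estimated correlation the list was not called even with all libraries (adjusted p = 0.625). For shorter dissociation, 5 heat shock genes had a median of 0.151, which met the bound written beforehand against it, a median above 0. That bound held no spread, and the SD of the 5 genes, 0.466, was larger than their median, so the question was left undecided. Shorter dissociation may still account for the pattern, and a difference with age stays open as well.

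Other splits of the libraries were counted beside the real one. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real count was 23 genes and the highest other 3 for 24 against 2 months, 105 and 1 for 12 against 2 months, and 66 and 0 for 24 against 12 months, so that 1 split reached the real count in each. For lists the real and highest other counts were 23 and 22, 15 and 22, and 20 and 25, with 1, 3 and 3 splits as large as the real one. Some splits that mix the ages thus gave nearly as many list calls at the preset correlation as the real grouping, or more. For the F test 2 of 100 splits gave as many genes, the real one with 110 and the highest other with 185. The share is under 0.05, which argues against chance at that level. It cannot tell age from any other difference between the 3 groups of libraries. The split with 185 kept the 3 libraries of 2 months together, as did 3 others that gave 1 gene each. For the linear trend the real count was 0, which each of the 100 orders reaches by construction, so their number, 100, says nothing about chance. The highest other order gave 214 genes and the next 9. The order with 214 set the 3 libraries of 2 months at one end and mixed the 12-month and 24-month libraries in the other groups, and another order that did so gave 1.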
